A study of Homo sapiens with 4 samples.

How the data were processed

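Gene expression was measured in NB-1, an established human neuroblastoma cell line, on 4 single-colour Agilent 8x60K human arrays. The deposited labels name 1 array for mock treatment, 1 for 5-aza-dC, 1 for TBT and 1 for the combination, and groups were taken from the treatment label. The treatment text is the same for every sample. It gives 0.3 µM 5-aza-dC for 3 days followed by 1 µM TBT for 4 days, and does not state the schedule of each single treatment. The labels do not spell out TBT. All 4 arrays lie on 1 slide with 1 scan time, per the file headers, so neither could be a batch. Cy3-labelled cRNA was made from 200 ng of total RNA and 600 ng was hybridised, per the labels. Each group is 1 array, so nothing measures the spread between cultures, and the number of arrays limits the precision.

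The deposited scanner files hold intensity values made by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal is the background-subtracted intensity of a spot, never negative here, and each spot carries a flag for being well above background. The array design is annotated on the GRCh37 build, per the file headers, and no coordinates were used. Each array has 58717 non-control spots of 50599 probes. 58.4% of spots were well above background on the mock array, 56.0% on the 5-aza-dC array, 65.8% on the TBT array and 50.8% on the combination array. No spot was saturated. The authors' deposited series table holds log2 values whose scale is not stated. Set against the scanner files, it equals the log2 processed signal minus a constant per array, with no centring by gene, so scale, centring and direction are settled. Its column medians were -3.70, -3.71, -2.55 and -3.72 for mock, 5-aza-dC, TBT and combination.

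The value used was the log2 processed signal minus that array's 75th percentile over non-control spots. Signals are printed in scaled units, in which the 75th percentile of every array is set to the mean of the 4 on the log scale. Spots flagged as outliers were left out and spots of 1 probe were averaged, which left 50353 probes and dropped 246. Probes were named by matching their accession, without version, to RefSeq accessions of the GRCh38.p14 assembly, used for names alone. 28070 probes matched and 22283 did not. Of 25132 probes with an mRNA accession, 24461 matched. The named probes covered 20440 genes, of which 5741 had several probes. A gene is represented by its probe with the highest mean value over the 4 arrays, and how its second brightest probe read is given per comparison. XIST, genes of the Y chromosome and some other genes are not reported here. A probe well above background on 1 of 2 arrays has only a bound. The dim side was then set to the higher of its own value and the lowest value well above background on that array, and the difference is given as "at least". A probe that was dim on both arrays gave no difference. Shares of a gene list below are of its measured members, so members dim on both arrays are left out and not counted as unchanged. A probe well above background on 1 array alone enters through that array and cannot read lower there, which shapes the counts of higher and lower genes.

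With 1 array per group no difference has replicates, and no p-value was computed. A gene was called by size alone, at a log2 difference of at least 1 (2-fold). 5 comparisons were made: each treatment against mock, and the combination against each single treatment. The combination was also set against the additive value, the sum of both single differences on the log2 scale. Calls of 1 compound were counted both without and with the other, using pairs of arrays that share none. Comparisons that share the mock array were set beside 100 simulated sets of unchanged groups against 1 shared array. 22 gene lists were fixed before the data were examined: cancer-testis antigens, germline genes, protocadherin beta and gamma, genes known to be methylated in neuroblastoma, interferon response, MHC class I antigen presentation, p53 targets, cell proliferation, MYC and MYCN targets of ribosome biogenesis and metabolism, retinoic acid response, HOX genes, neuronal differentiation, adrenergic neuroblastoma identity, mesenchymal neuroblastoma cells and fibroblasts, Schwann and glial cells, DNA methylation and 5-aza-dC metabolism, apoptosis, integrated stress response and endoplasmic reticulum stress, hypoxia and glycolysis, cholesterol synthesis, replication-dependent histones, and genes that every cell uses. For each list the median difference and its percentile among 10000 random lists of the same size, matched on mean value in 20 bins, describe these arrays and are not a test of the treatments. The named genes follow a rule written before the data were examined: the 10 furthest higher and lower per comparison, without uncharacterised loci, and up to 4 members of each list. Genes named outside that rule are said to be so.

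The precision within an array was taken from 902 probes with 10 spots each. Their log2 SD had a median of 0.088 over all brightness classes and arrays, which gives 0.124 for a difference between 2 single spots. For bright probes it was 0.0583 on the mock array, and for dim probes 0.266. The steps were tested on simulated data made from the mock array with this within-array spread. For 5-aza-dC against mock, over 20440 genes, 0 of 50 genes changed 1.5-fold were called at 2-fold. All 50 of 50 were called at each of 2.5-fold, 4-fold and 8-fold, with 19 false calls among unchanged genes. For TBT against mock, 5 of 200 unshifted lists lay outside percentiles 2.5 to 97.5, as did 50 of 50 lists shifted by 0.3. The changed genes and the shifted lists were drawn from brighter genes, and every simulated array had the dim signal of the mock array. How genes on a bound, or a raised dim signal on 1 array, affect calls and percentiles was therefore not tested. The simulation holds no spread between cultures.

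Alternatives planned before the data were examined were normexp background correction with an offset of 50, quantile normalization, a 75th percentile over probes well above background on all 4 arrays, the authors' deposited table, probes well above background on every array compared, no filter on dim probes, a 3-fold threshold, and the mean of a gene's probes. The files hold a median and no mean spot brightness, so normexp used the median spot and background brightness. Both of 2 further alternatives were chosen after seeing the data: every scaled signal below 100 units raised to 100, and leaving out genes bright on 1 array alone. The last are genes whose probe read over 1.5 log2 units above each of the other 3 arrays and over 200 units. Work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.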

Results

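Transcripts of NB-1 cells were compared after mock treatment, 5-aza-dC, TBT and both compounds, with 1 array for each. 5-aza-dC is a cytidine analogue that traps DNA methyltransferases and lowers DNA methylation. By the series title, the comparisons ask which genes differ after each compound and after the combination. Every value below rests on 1 array per group, so no difference has a replicate check, and "higher" and "lower" describe these arrays. 15318 genes could be compared between 5-aza-dC and mock, and 14925 genes were well above background on the mock array, 14627 on the 5-aza-dC array, 15906 on the TBT array and 13739 on the combination array.

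Dim probes read higher on the TBT array than on the other 3. The dim spike-in r60_a104, an RNA added to every labelling reaction in a fixed amount, had a median processed signal of 61.4 units on the TBT array, 3.86 on the mock array, 5.20 on the 5-aza-dC array and 10.5 on the combination array. Spike-in r60_a135 read 341, 359, 378 and 353 units on mock, 5-aza-dC, TBT and combination. The first quartile of the processed signal was 24.2 units on the TBT array and 4.26 on the mock array. Total counts of called genes that use the TBT array are therefore printed also with every scaled signal below 100 units raised to 100, an alternative chosen after seeing the data.

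**Figure D1:**
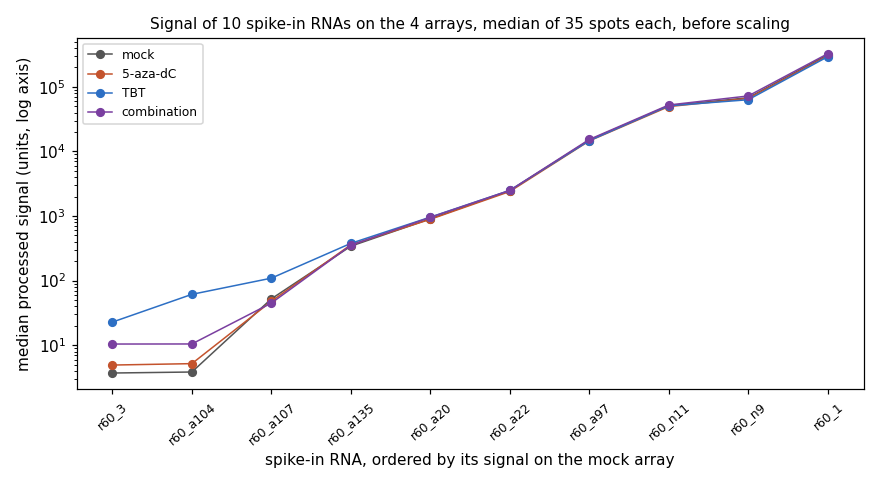
Median processed signal (units, log axis) of 10 spike-in RNAs on each of the 4 arrays, ordered by their signal on the mock array; each point is the median of 35 spots on 1 array. The lines overlie each other from r60_a135 upwards, while the dimmest spike-ins lie highest on the TBT array, with r60_a104 at 61.4 units there and 3.86 units on the mock array.

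After 5-aza-dC alone, cancer-testis antigens lay furthest above mock. These genes are normally read in germ cells and are silenced in most other cells. PAGE2B was at least 1469.6-fold higher, at 25889.7 scaled units under 5-aza-dC and not well above background under mock, and PAGE2 was at least 1154-fold higher. CTAG1A, one of the genes for the NY-ESO-1 antigen, was at least 344-fold higher, MAGEA2B at least 261-fold, SSX4B at least 115-fold, CTAG2 at least 89.2-fold and MAGEA9 at least 70.2-fold. VCX2 was well above background on both arrays and was 142-fold higher (143 to 20378 units), MAGEB2 94.4-fold and the transketolase-like gene TKTL1 77.8-fold. Of the fixed cancer-testis list, 21 of 22 measured members were at least 2-fold higher and 0 lower, with median log2 difference 3.71, percentile 100, or 14 higher and a median of 2.31 with signals below 100 units raised to 100. Of the list's 35 symbols, 22 matched a named probe and 11 were well above background under mock. The other measured members entered through the 5-aza-dC array and could not read lower. Near-identical copies in these families may share probes, so single members are uncertain.

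Interferon response genes had the next highest list median: 40 of 43 measured members were at least 2-fold higher under 5-aza-dC, with median log2 difference 1.49, percentile 100. TRIM22 read 31.3 units under mock and 503 under 5-aza-dC. RSAD2 (viperin) had a log2 difference of 2.67, IFI35 2.65 and PARP14 at least 2.96. In the MHC class I antigen presentation list 7 of 20 were at least 2-fold higher (median log2 difference 0.65, percentile 100), led by HLA-C (1.27), the peptide transporter TAP1 (1.26), HLA-E (1.17) and HLA-G (1.14). Of 32 p53 targets, 4 were higher (median log2 difference 0.45, percentile 100). They were TRIM22, also on the interferon list, the death receptor FAS (1.73), the cell cycle inhibitor CDKN1A (1.07) and GDF15 (1.04). In the apoptosis list, 4 of 35 were higher (median log2 difference 0.098, percentile 99.96): TNFSF10, the death ligand TRAIL (at least 3.28), BIK (2.06), FAS, and BIRC3 (at least 1.32). After the raise to 100 units 2 of these were called, not TNFSF10 or BIRC3, and PARP14 lost its call as well.

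Other lists with genes known to be silenced by methylation were mixed. Among germline genes 8 higher, 0 lower and 8 neither of 16 measured were seen (median log2 difference 0.63, percentile 99.93). The list had 35 members with a named probe. Those dim on both arrays gave no difference and are left out of the 16. Of the germline list 8 were well above background under mock. The rest of the 16 entered through the 5-aza-dC array and could not read lower. GTSF1, MAEL and PIWIL4, all of the piRNA pathway, were higher by at least 6.13, 3.87 and 2.97 on the log2 scale. TDRD6 was also higher, by at least 5.12, on the 5-aza-dC array and on no other. Of the protocadherin beta and gamma list, 31 members had a named probe and 21 were measured. Of the 21, 5 were higher (median log2 difference 0.55, percentile 100), with PCDHB5 at 2.88 and PCDHB15 at 2.35. With signals below 100 units raised to 100, the germline median was 0 and the protocadherin median 0. Of genes known to be methylated in neuroblastoma, 6 of 20 were higher and 1 lower (median log2 difference -0.036, percentile 60.9). DUSP23 was higher by at least 5.77, EMP3 by 2.37 and the inflammasome adaptor PYCARD by at least 2.35. The 1 lower gene was MYOD1, the muscle transcription factor, at -5.89 (1745 units on the mock array and 29.4 on the 5-aza-dC array), on a probe bright on the mock array alone. Of the list for mesenchymal neuroblastoma cells and fibroblasts, 6 of 33 were higher and 1 lower (median log2 difference 0.14, percentile 99.87), with S100A6 at least 4.56, ACTA2 1.75 and the surface receptor CD44 1.72. For Schwann and glial cells, 2 of 10 were higher (median log2 difference 0.15, percentile 88.8), among them MBP by at least 2.82. After the raise to 100 units the germline list had 3 higher, the protocadherin list 1, the methylated list 5, the mesenchymal list 3 and the Schwann and glial list 1, and PIWIL4, PCDHB15, PYCARD, ACTA2 and MBP lost their calls.

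Hypoxia and glycolysis genes were lower under 5-aza-dC: 8 of 27 by at least 2-fold and 0 higher (median log2 difference -0.75, percentile 0). The combination against TBT, which does not use the mock array, also had this list lower, with a smaller median and fewer calls. How much of the fall against mock comes from a high reading of the mock array cannot be told. The carbonic anhydrase CA9 was at least 14.3-fold lower, its probe being bright on the mock array alone. Adrenomedullin (ADM) had a log2 difference of -2.32, NDRG1, also bright on the mock array alone, -2.13 and aldolase C (ALDOC) -1.81. ANGPTL4, which inhibits lipoprotein lipase, was 15.1-fold lower (7628 to 506 units), again on a probe bright on the mock array alone. In cholesterol synthesis 6 of 23 were lower (median log2 difference -0.65, percentile 0), with HMGCS1 at -1.20, MVD -1.19, INSIG1 -1.17 and FDFT1 -1.14. Replication-dependent histones had 1 higher, 2 lower and 29 neither (median log2 difference -0.61, percentile 0), where the higher gene, H1-1, stood at least 4.84 above mock. Of 48 cell proliferation genes none reached 2-fold, yet 46 were below mock (median log2 difference -0.40, percentile 0), MCM5 at -0.82 and MCM6 at -0.76. MYC and MYCN targets of ribosome biogenesis and metabolism likewise had 0 calls among 35 (median log2 difference -0.30, percentile 0.330). The integrated stress response and endoplasmic reticulum stress list had 1 higher, 3 lower and 33 neither (median log2 difference -0.23, percentile 2.48), with the mTORC1 inhibitor DDIT4 at -1.83.

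Neuronal and lineage lists had small medians after 5-aza-dC. The neuronal differentiation list had 3 higher, 2 lower and 49 neither (median log2 difference -0.18, percentile 4.92), with neurofilament NEFM at -1.35, peripherin (PRPH) at 1.31 and SCG5 at 1.24. The adrenergic neuroblastoma identity list had 1 higher, 1 lower and 30 neither (median log2 difference 0.046, percentile 99.74), where the lower gene was the Notch-family ligand DLK1 (-3.04) and the higher gene the neuroblastoma oncogene LMO1 (2.20). Among HOX genes 3 higher, 1 lower and 16 neither of 20 were seen (median log2 difference -0.23, percentile 2.16), with HOXA9 at 1.31. The retinoic acid response list had 3 higher, 4 lower and 22 neither (median log2 difference -0.24, percentile 1.82), from TNFAIP2 at 3.33 and ICAM1 at 2.24 to the retinaldehyde reductase DHRS3 at -2.19. After the raise to 100 units the neuronal list had 2 higher (not SCG5), the HOX list 2 higher and 0 lower, and the retinoic acid list 2 higher (not ICAM1) and 2 lower, with medians of -0.038, 0 and 0. Relative to matched random lists, the retinoic acid list turned above 0 under 4 alternative settings and the HOX list under 1. No member of the list for DNA methylation and 5-aza-dC metabolism was called among 25 (median log2 difference -0.097, percentile 54.2), with DNMT3B at -0.70 and UHRF1 at -0.62. The 29 genes that every cell uses had 0 calls (median log2 difference -0.22, percentile 33.3).

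In all, 711 genes were at least 2-fold higher and 283 lower under 5-aza-dC than under mock, of 15318 measured, and 348 of these calls rest on a bound. With signals below 100 units raised to 100, they were 306 and 126. The other genes furthest below mock by the naming rule were MYOZ1, PLPP3 (-3.66 and -3.28) and, on a bound, TMPRSS11A, UGT2A3, CAPN13, WFDC10B and NR5A2 (from -3.63 to -3.32). All 10 genes furthest below mock, MYOD1, ANGPTL4 and CA9 included, read over 1.5 log2 units brighter on the mock array than on each of the other 3. None of the 10 furthest above mock was bright on 1 array alone. Of the called genes with a second measured probe, 84 of 102 called higher had the same sign there (60 by at least 2-fold) and 34 of 38 called lower had the same sign there (8 by at least 2-fold).

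**Figure D2:**
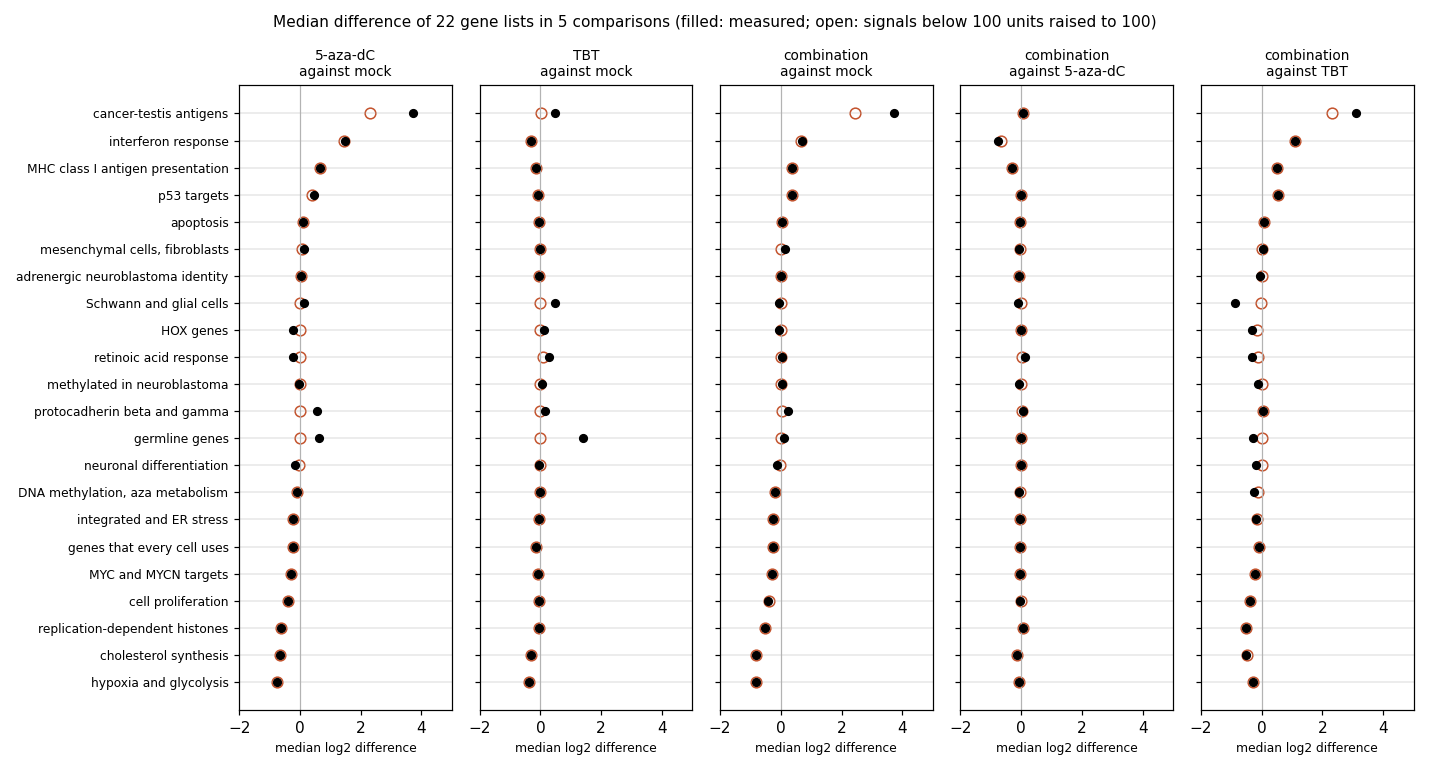
Median log2 difference (x axis) of the 22 fixed gene lists (y axis) in the 5 comparisons, 1 array against 1; filled points are the values as measured or bounded, open points those with signals below 100 units raised to 100. Cancer-testis antigens lie at 3.71 under 5-aza-dC and 3.74 under the combination, and the interferon list lies at 1.49 under 5-aza-dC and 0.70 under the combination, both against mock.

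After TBT alone, genes of the retinoic acid response list were higher than under mock. DHRS3, which reduces retinaldehyde to retinol, read 2292 units against 430.2 under mock and was well above background on all 4 arrays. CYP26B1 and CYP26A1, which degrade retinoic acid, were not well above background under mock and were higher by at least 4.03 and 3.19 on the log2 scale. CYP26B1 read 265 units, on a probe bright on the TBT array alone, and CYP26A1 148 under TBT. RARRES2 stood at least 3.04 and the transcription factor TFAP2A 2.85 above mock. Of the list, 12 of 34 were at least 2-fold higher and 1 lower (median log2 difference 0.28, percentile 100), and 3 were higher and 0 lower after the raise to 100 units (median 0.091, percentile 100). CYP26A1, RARRES2 and TFAP2A were not among those 3.

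Interferon response genes were lower under TBT than under mock, with 34 of 43 below it and median log2 difference -0.31, percentile 0. 3 were at least 2-fold lower: OAS2, an antiviral oligoadenylate synthase (-1.29), IFI44L (-1.09) and IFITM1 (-1.08). EPSTI1 was higher, by at least 1.17, from a dim reading under mock, and not after the raise to 100 units. MHC class I genes had 0 calls and 19 of 20 below mock (median log2 difference -0.15, percentile 4.12), about as genes that every cell uses, with 26 of 29 below mock (median log2 difference -0.16, percentile 5.29). Hypoxia and glycolysis genes were lower too: all 27 measured members were below mock and 4 by at least 2-fold (median log2 difference -0.37, percentile 0), which were ADM (-1.81), NDRG1 (-1.67), CA9 (-1.61) and PFKFB4 (-1.19). NDRG1 and CA9 were bright on the mock array alone. In the combination against 5-aza-dC, which does not use that array, the list had 0 calls (median log2 difference -0.073). A high reading of the 1 mock array cannot be told apart from an effect of TBT on this list. Cholesterol synthesis genes had 0 calls and 22 of 23 below mock (median log2 difference -0.30, percentile 0), with INSIG1 at -0.56. The haem oxygenase gene HMOX1 had a log2 difference of -0.97, the pro-apoptotic gene BAX -0.78 and DLK1 -1.29. Cell proliferation genes (-0.032) and replication-dependent histones (-0.039) lay near mock.

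2327 genes were at least 2-fold higher and 80 lower under TBT than under mock, of 16536 measured, and 1652 calls rest on a bound. With signals below 100 units raised to 100 they were 87 and 37, and with quantile normalization 727 and 1238, which puts more genes lower than higher. Of the called genes with a second measured probe, 174 of 201 called higher had the same sign there (156 by at least 2-fold) and 3 of 13 called lower had the same sign there (2 by at least 2-fold). A rise of dim probes across the TBT array would lift second probes too. The agreement of the higher calls therefore cannot tell such a rise from a response of the genes. Cancer-testis antigens had a median of 0.49 over 12 measured, or 0.012 after that raise, with 5 and 0 called higher. Germline genes had 9 and 0. By the naming rule, the genes furthest above mock were SNORD113-9 (at least 6.01), OR52B4, ACTL9, MGAM, SSMEM1, ZNF582, KCNMB2, CALCA, CYP26B1 and OR4D11 (at least 4.01). All 10 read over 1.5 log2 units brighter on the TBT array than on each of the other 3. Those furthest below mock were MYOD1 (-3.69), TMPRSS11A, UGT2A3, WFDC10B, MYOZ1, PPL, NR5A2, KCNH5, F8 and ABCC9 (at or below -2.35), of which all but KCNH5 and ABCC9 were bright on the mock array alone.

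Under the combination, which asks what both compounds give together, cancer-testis antigens again lay furthest above mock. PAGE2B was at least 1709-fold higher, PAGE2 at least 1164-fold, CTAG1A at least 371-fold, MAGEA2B at least 297-fold, VCX2 143-fold, SSX4B at least 111-fold, MAGEB2 108-fold, CTAG2 at least 102-fold and MAGEA12 at least 79.9-fold. Among them ranked the transketolase-like gene TKTL1, 82.2-fold higher. All 22 of 22 measured cancer-testis antigens were at least 2-fold higher (median log2 difference 3.74, percentile 100), or 15 after the raise to 100 units (median 2.44). Interferon response genes had 14 of 43 higher (median log2 difference 0.70, percentile 100), with TRIM22 at 3.11, the chemokine CXCL10 at 1.76 and IFI35 at 1.72. The retinoic acid list had 5 higher, 1 lower and 24 neither (median log2 difference 0.039, percentile 99.68): TNFAIP2 stood at 3.57, DHRS3 at 2.29 and CYP26B1, brightest on the TBT array, at least at 2.38. After the raise to 100 units it had 3 higher and 0 lower (median 0, percentile 75.4), and CYP26B1 lost its call.

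Hypoxia and glycolysis genes and cholesterol synthesis genes were lower under the combination as well, against the same mock array. 9 of 27 hypoxia and glycolysis genes were at least 2-fold below mock (median log2 difference -0.82, percentile 0), with ADM at -2.79, PFKFB4 at -2.19 and NDRG1 at -1.96. 8 of 23 cholesterol synthesis genes were (median log2 difference -0.80, percentile 0), with INSIG1 at -1.42. Cell proliferation genes had 0 calls and a median of -0.42. IGF2, the insulin-like growth factor gene, was 8.05-fold lower (68711 units under mock, 8539.9 under the combination), and DLK1 9.54-fold. The others furthest below mock were MYOD1, LETR1, ANGPTL4, MYOZ1, PLPP3, KCNH5, CA9 and F8. Of these, LETR1 read 15.2 units on the combination array and 632 under mock, and the rest but KCNH5 were bright on the mock array alone. In all, 714 genes were higher and 309 lower of 15173, or 335 and 177 with signals below 100 units raised to 100. Of the called genes with a second measured probe, 70 of 104 called higher had the same sign there (51 by at least 2-fold) and 28 of 41 called lower had the same sign there (13 by at least 2-fold).

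Set against 5-aza-dC alone, which asks what TBT adds, the combination had lower interferon response genes. 41 of 43 lay below 5-aza-dC and 11 by at least 2-fold (median log2 difference -0.75, percentile 0). XAF1 was at -1.54 on a probe bright on the 5-aza-dC array alone, while its second probe read 392 units there and 138 in the combination. SAMD9 was at -1.49 and OAS1 at -1.38. OAS2 read 875 units under mock, 2294 under 5-aza-dC, 358 under TBT and 994 under the combination. All 20 MHC class I genes were below 5-aza-dC, none by 2-fold (median log2 difference -0.31, percentile 0), with TAP1 at -0.67. DHRS3 was 22.3-fold higher in the combination (94.5 to 2103 units), CYP26B1, brightest on the TBT array, at least 2.06 higher on the log2 scale, RARB, a retinoic acid receptor, 1.35 and HOXA2 1.08. Those were the 4 members of the retinoic acid list called higher, of 26 measured (median log2 difference 0.13, percentile 100). After the raise to 100 units DHRS3 alone was called (median 0.021), and of the interferon list 9 were, without SAMD9. Cancer-testis antigens had 0 calls (median log2 difference 0.072, percentile 99.02), cholesterol synthesis had 0 (median log2 difference -0.14, percentile 0) and hypoxia and glycolysis 0 (median log2 difference -0.073, percentile 8.79). HMOX1 had a log2 difference of -0.76 and BAX -0.29.

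In all, 283 genes were higher and 112 lower in the combination than under 5-aza-dC, of 14804, or 106 and 47 with signals below 100 units raised to 100. Of the 283, 71 were bright on 1 array alone. Of the called genes with a second measured probe, 13 of 27 called higher had the same sign there (4 by at least 2-fold) and 10 of 14 called lower had the same sign there (4 by at least 2-fold). By the naming rule the furthest higher were ANOS1 (4.81), TNFRSF1B (at least 4.70), SFTPD, COL6A4P2, HIF3A, DHRS3, RLN1, CHRDL1, DHRS7C and CLEC18B (4.04), and all but DHRS3 were bright on the combination array alone. A second probe of ANOS1 read 34.1 units on the combination array, where the named probe read 8565. The furthest lower were PAX3 (at or below -4.64), TDRD6, LETR1, SNORD84, ZFR2, HOXB9, PNLIPRP1, TAS2R50, MYBPC1 and ADAMTS14 (at or below -2.57), and all but LETR1 and MYBPC1 were bright on the 5-aza-dC array alone.

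Set against TBT alone, which asks what 5-aza-dC adds, the combination had the cancer-testis antigens again at the top: PAGE2B was 568-fold higher, PAGE2 394-fold, VCX2 98.7-fold and SSX4B 38.2-fold. Among them ranked the transketolase-like gene TKTL1, 67.1-fold higher. On a bound, CTAG1A was at least 171-fold higher, the probe of MAGEA2B at least 141-fold, MAGEB2 at least 54.1-fold, CTAG2 at least 46.7-fold and MAGEA12 at least 36.8-fold. Of the list 18 of 22 were higher (median log2 difference 3.12, percentile 100), or 15 with signals below 100 units raised to 100. 23 of 44 interferon response genes were higher (median log2 difference 1.11, percentile 100), with TRIM22 at 2.80, the RNA sensor IFIH1 at 1.96 and RSAD2 at 1.82. 3 of 27 hypoxia and glycolysis genes were lower (median log2 difference -0.30, percentile 0.340): CA9 (at or below -1.44), ALDOC (-1.17) and PFKFB4, of which 2 were left after that raise. Cholesterol synthesis had 1 lower, MVD at -1.15 (median log2 difference -0.51, percentile 0). The catecholamine synthesis enzyme TH stood at 1.09, LMO1 at 2.01, CHGB at -1.23 and NEFM at -1.53. The furthest lower by the naming rule were SNORD113-9, LETR1, OR52B4, ACTL9, SSMEM1, KCNQ5, FAM161B, MGAM, ZNF582 and MOGAT1, on bounds from -4.89 to -3.40, and all but LETR1 were bright on the TBT array alone.

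In that comparison 499 genes were higher and 1370 lower of 16181. The split differed between settings: it was 330 and 218 with signals below 100 units raised to 100, and 1071 and 541 with quantile normalization. Those settings raised the median difference of all genes by 0.14 and 0.15. Of the called genes with a second measured probe, 58 of 102 called higher had the same sign there (36 by at least 2-fold) and 134 of 147 called lower had the same sign there (65 by at least 2-fold). Second probes would share a rise of dim probes on the TBT array, so the agreement of the lower calls cannot tell such a rise from an effect.

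**Figure D3:**
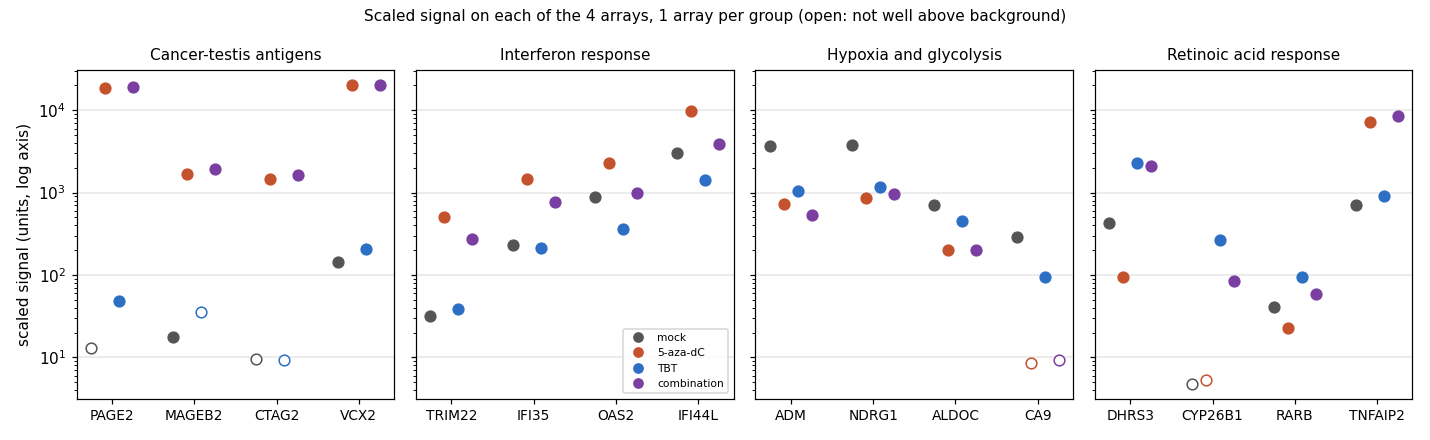
Scaled signal (units, log axis) of genes from 4 groups, 1 point per array coloured by treatment; open points were not well above background. TRIM22, IFI35, OAS2 and IFI44L are highest under 5-aza-dC and lower under the combination, DHRS3 is at 2292 and 2103 units on the arrays with TBT, and CA9 reads 291 units under mock.

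The 5-aza-dC effect was measured on separate pairs of arrays without TBT (5-aza-dC against mock) and with it (combination against TBT). 291 genes were at least 2-fold higher on both pairs, where 16.7 were expected if the calls were independent, and 115 were lower on both, where 12.4 were. With signals below 100 units raised to 100 the counts were 201 and 57. Across 14600 genes, which are not independent replicates, the differences had a Pearson correlation of 0.65 and a Spearman correlation of 0.60. The TBT effect without 5-aza-dC (TBT against mock) and with it (combination against 5-aza-dC) had 89 genes higher on both pairs (8.51 expected if independent) and 6 lower (0.262 expected), with a Pearson correlation of 0.19 and a Spearman correlation of 0.067. In these counts and those below, a gene dim on every array without the compound is measured on both pairs only if well above background on both arrays with it. This links the calls, so counts expected if independent are not values for unchanged genes. With the raise to 100 units the Pearson and Spearman correlations for TBT were 0.084 and 0.10. 2 genes were then higher on both pairs, DHRS3 (2.41 and 4.39) and the lens crystallin CRYGC, at 105 units under mock, 61.6 under 5-aza-dC, 418 under TBT and 332 under the combination. 3 were lower, OAS2 (-1.29 and -1.21), IFI44L (-1.09 and -1.30) and IFITM1 (-1.08 and -1.36). CRYGC was named after its values were seen.

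5-aza-dC and TBT were each set against the same mock array, and this by itself links their differences. Across 15047 genes the Pearson correlation was 0.30 and the Spearman correlation 0.29. Unchanged groups of equal spread against 1 shared array give a simulated Pearson correlation of 0.50 by construction, so that value is no benchmark for these arrays. The covariance was 0.0807 against a simulated 0.0510. The simulation drew normal noise with a spread taken from departures from the additive value, which hold interactions too. It does not represent probes bright on the mock array alone, so an excess over it cannot be assigned to the compounds. 136 genes were higher after both compounds (29.7 expected if independent) and 64 lower (1.5 expected). With signals below 100 units raised to 100 they were 6 and 29 (1.23 and 0.310 expected), with a covariance of 0.0248 against a simulated 0.00835. With 1 mock array the controls could not be split, and part of the excess may come from the shared array. For 5-aza-dC and the combination the Pearson correlation was 0.86, with a covariance of 0.321 against the first simulated value, 0.0510, and 406 genes were higher and 185 lower against mock in both. After the raise to 100 units these were 205 and 105, with a covariance of 0.173. For TBT and the combination the Pearson correlation was 0.36, with a covariance of 0.0993, and 162 and 68 genes, or 7 and 30 with a covariance of 0.0289 after the raise to 100 units.

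**Figure D4:**
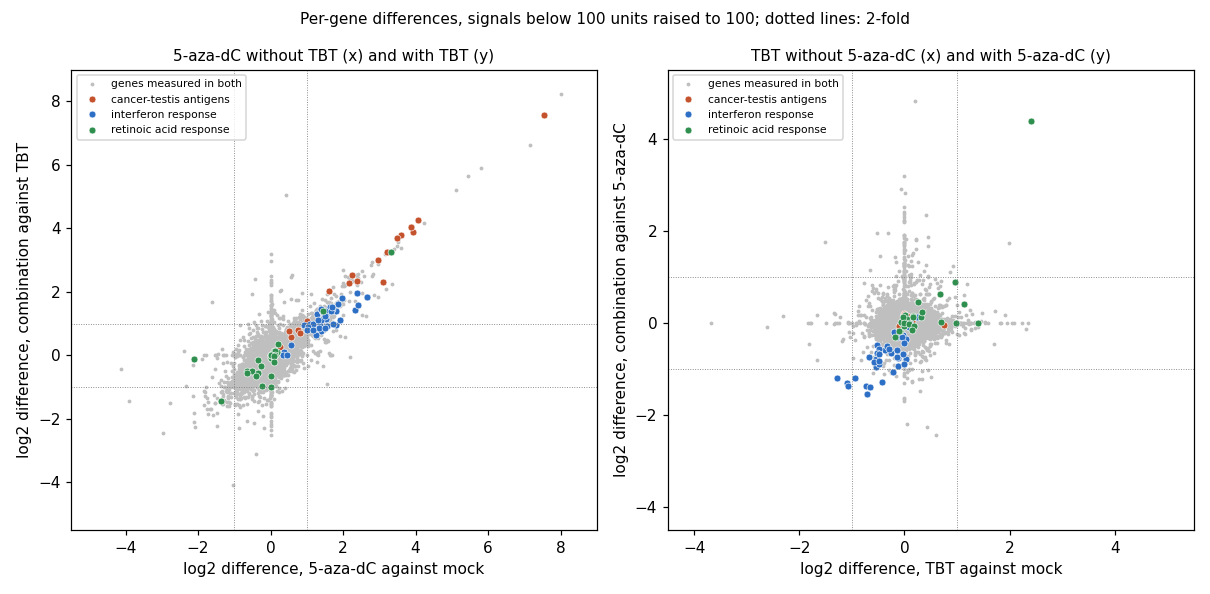
Log2 difference of each gene without the other compound (x axis) and with it (y axis), for 5-aza-dC on the left and TBT on the right, with signals below 100 units raised to 100; each grey point is 1 gene and coloured points are members of 3 fixed lists. Cancer-testis antigens and most interferon genes lie above 0 on both axes for 5-aza-dC, and for TBT most interferon genes lie below 0 on both axes while DHRS3 lies at 2.41 and 4.39.

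Against the additive value, interferon response genes in the combination were lower than the sum of the single differences: 40 of 44 were below it and 4 by at least 2-fold (median log2 difference -0.28, percentile 0), though 0 by 2-fold with signals below 100 units raised to 100 (median -0.26). Hypoxia and glycolysis genes were above it, all 27 measured (median log2 difference 0.38, percentile 100), with 3 by at least 2-fold. Cholesterol synthesis genes were above it in 21 of 23 (median log2 difference 0.15, percentile 99.82). The mock array enters this value for every gene, and NDRG1 and CA9 of the hypoxia list were bright on it alone. Cancer-testis antigens had a median of -0.95, which turned to 0.046 with signals below 100 units raised to 100. The furthest above were ANOS1, LRRC2, MYOD1, TMPRSS11A, HIF3A, UGT2A3, CLEC18B, WFDC10B, ZNF718 and NR5A2 (4.61 to 3.31). All but LRRC2 were bright on 1 array alone. The furthest below were PAX3, SNORD113-9, TDRD6, ZFR2, OR52B4, ACTL9, HOXB9, LETR1, MST1P2 and CRMA (-5.64 to -4.18), and all but LETR1, MST1P2 and CRMA were bright on 1 array alone. In all, 287 genes lay at least 2-fold above and 1808 below the additive value of 16899. The split was 148 and 137 with signals below 100 units raised to 100, and 1849 and 521 with quantile normalization.

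**Figure D5:**
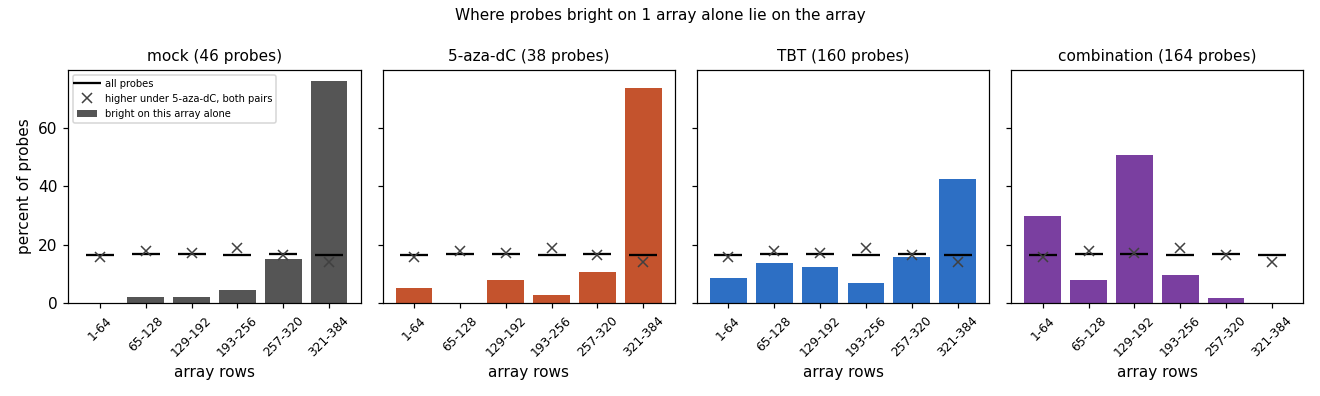
Share (percent, y axis) of probes bright on 1 array alone that lie in each sixth of the array's rows (x axis), one panel per array; black marks are all probes and crosses are probes at least 2-fold higher under 5-aza-dC on both pairs of arrays. Of these probes 76.1% on the mock array and 73.7% on the 5-aza-dC array lie in rows 321 to 384, which hold 16.4% of all probes.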

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

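All tests in this part were chosen after the values they measure had been seen. The differences between pairs of arrays given first were not tested.

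26 genes were at least 2-fold higher under 5-aza-dC without TBT and at least 2-fold lower with it, HLA-DPB1, ITGA3 and RHOXF1 among them, and 3 genes (LOC100507547, LRRC2 and SAMD4A) did the opposite. 15 genes, S100A8, TAL1 and APOBEC3G among them, were at least 2-fold higher under TBT without 5-aza-dC and lower with it, and 1 gene, LOC100507547, did the opposite. Of 14600 genes measured on both 5-aza-dC pairs, 592 were higher without TBT and 805 lower with it, while 224 were lower without it and 412 higher with it. The 26 and 3 are no more than independent calls would give. For TBT, 661 of 14441 genes were higher without 5-aza-dC and 84 lower with it, and the 15 are more than independent calls would give. With signals below 100 units raised to 100, LOC100507547 is left in both comparisons, at 655 units under mock, 215 under 5-aza-dC, 230.0 under TBT and 731 under the combination. These genes were named after their values were seen. Among 7186 measured probes with no gene symbol, which enter no comparison above, 71 were at least 2-fold higher under 5-aza-dC both without and with TBT, where 7.64 were expected if the calls were independent. 96 were at least 2-fold lower on both, for which no expected count was computed. The filter on dim probes links these calls as well. The counts were 38 higher and 17 lower with signals below 100 units raised to 100.

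The first pattern is the excess of higher over lower calls on the TBT array against mock, 2327 against 80. Of the higher calls, 661 could be measured in the combination against 5-aza-dC, and 13.5% of these were at least 2-fold higher there. Genes of these 661 well above background on the 5-aza-dC array and not on the combination array could not read higher in the combination. They were not counted, so the 13.5% cannot decide for or against a response to TBT seen both without and with 5-aza-dC. The higher calls outside the 661 were dim on both of those arrays. The 13.5% are 89 genes, or 2 with signals below 100 units raised to 100. They exceed the 8.51 expected if the calls were independent, but the filter on dim probes links the calls. That excess therefore does not speak for a shared response. A raised signal of dim probes on that array is a candidate explanation: 3.74% of the higher calls were left once signals below 100 units were raised to 100. That raise would also remove real increases of dim genes, so by itself it cannot tell these apart. The spike-in r60_a104, which does not come from the cells, read 61.4 units on the TBT array and 10.5 on the combination array, whose cells also had TBT. On the mock and 5-aza-dC arrays it read 3.86 and 5.20 units, so the combination array was raised for it as well, by less. A response of dim genes to TBT, whether 5-aza-dC prevents it or the combination array could not measure it, stays open and was not tested.

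The second pattern is that many of the genes furthest from another array were bright on 1 array alone. In the fullest sixth of array rows lay 76.1% of such probes on the mock array and 73.7% on the 5-aza-dC array (rows 321 to 384 in both), 42.5% on the TBT array (the same rows) and 50.6% on the combination array (rows 129 to 192). All probes had 16.4% in rows 321 to 384 and 16.8% in rows 129 to 192, and the 402 probes higher under 5-aza-dC on both pairs had 13.9% and 17.2%. For the 67 genes with a second measured probe, a response of the gene is argued against for them as a set. That probe was also at least 2-fold brightest on the same array in 5 of them (7.46%). The whole set is larger, with 160 such probes on the TBT array and 164 on the combination array. A local effect of array position may account for part of this set, and single members with no second measured probe stay open: ANGPTL4 lies in row 365, inside the fullest sixth of its array, while CA9 (row 83) and CYP26B1 (row 79) lie outside theirs. ANGPTL4 was also lower in the combination than under TBT, a pair without the mock array (1528 to 559 units, log2 difference -1.45). That fall was smaller than the one from mock to 5-aza-dC (-3.91).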

How the results depend on the processing

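No paired analysis was possible because each group has 1 array and the labels carry no shared replicate numbers. Leaving out a replicate was not possible for the same reason. The 75th percentile over probes well above background on all 4 arrays, the authors' deposited table, the mean of a gene's probes, and leaving out genes bright on 1 array alone each kept all 16 counts within 1.5 times. The last of these and the raise of signals below 100 units to 100 were chosen after seeing the data. Where a count moved under the other settings the cause was not tested, except that a 3-fold threshold and a filter on every array compared can only lower a count. Signal over background limits these counts: 1652 of the calls in TBT against mock rest on a bound. Normexp background correction gave 316 higher and 114 lower for 5-aza-dC against mock, 564 higher and 27 lower for TBT against mock, 348 higher and 175 lower for combination against mock. There were 129 higher and 56 lower for combination against 5-aza-dC, 273 higher for combination against TBT, 111 above and 788 below the additive value. It also gave 187 higher and 46 lower under 5-aza-dC on both pairs, 12 higher under TBT on both pairs. Quantile normalization gave 727 higher and 1238 lower for TBT against mock, 1071 higher and 541 lower for combination against TBT. There were 1849 above and 521 below the additive value, 29 higher and 25 lower under TBT on both pairs. Probes well above background on every array compared gave 466 higher and 180 lower for 5-aza-dC against mock, 716 higher and 39 lower for TBT against mock, 466 higher and 195 lower for combination against mock. There were 112 higher and 44 lower for combination against 5-aza-dC, 365 lower for combination against TBT, 101 above and 304 below the additive value. It also gave 69 lower under 5-aza-dC on both pairs, 17 higher and 3 lower under TBT on both pairs. No filter on dim probes gave 1154 higher and 831 lower for 5-aza-dC against mock, 5504 higher and 189 lower for TBT against mock, 3794 higher and 800 lower for combination against mock. There were 630 higher and 446 lower for combination against 5-aza-dC, 4132 lower for combination against TBT, 500 above and 4151 below the additive value. It also gave 557 lower under 5-aza-dC on both pairs, 444 higher and 17 lower under TBT on both pairs. A 3-fold threshold gave 334 higher and 114 lower for 5-aza-dC against mock, 1491 higher and 40 lower for TBT against mock, 424 higher and 101 lower for combination against mock. There were 46 lower for combination against 5-aza-dC, 243 higher and 400 lower for combination against TBT, 144 above and 697 below the additive value. It also gave 140 higher and 25 lower under 5-aza-dC on both pairs, 49 higher and 1 lower under TBT on both pairs. Signals below 100 units raised to 100 gave 306 higher and 126 lower for 5-aza-dC against mock, 87 higher and 37 lower for TBT against mock, 335 higher and 177 lower for combination against mock. There were 106 higher and 47 lower for combination against 5-aza-dC, 330 higher and 218 lower for combination against TBT, 148 above and 137 below the additive value. It also gave 57 lower under 5-aza-dC on both pairs, 2 higher and 3 lower under TBT on both pairs.

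List shifts are given here as the median minus that of matched random lists. In TBT against mock, cancer-testis antigens turned to -0.1357 with quantile normalization and -0.0227 with signals below 100 units raised to 100. Against the additive value they turned to 0.5857 and 0.0983. In 5-aza-dC against mock, the retinoic acid response list turned to 0.1294 with probes well above background on every array compared, 0.057 with no filter, 0.0838 with the mean of probes and 0.002 with the raise to 100 units. HOX genes turned to 0.0845 with no filter. HIF3A against the additive value turned to -0.84 with the mean of its probes. Of 325 calls of named genes, 250 were kept with normexp, 285 with quantile normalization and 237 with the raise to 100 units. No other list with a percentile outside the middle 95%, and no other named gene at least 2-fold apart, changed sign under the settings run. The cause of these turns was not tested.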

Other observations

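Genes outside the fixed lists also had the same direction under 5-aza-dC without and with TBT, and those named here were chosen after their values were seen. The imprinted neighbours IGF2 and H19 were lower on both pairs of arrays, IGF2 with log2 differences of -2.97 and -2.46 and H19 with -1.67 and -1.68. IGF2 read 68711 units under mock and 8777 under 5-aza-dC, and H19 87994 and 27609. The chemokines CCL3 and CCL4 were higher on both pairs (2.79 and 2.96 for CCL3 and 2.83 and 2.57 for CCL4, with signals below 100 units raised to 100), as were the leukotriene enzyme ALOX5 (103 units under mock and 719.7 under 5-aza-dC), the annexin partner S100A10 (3.49 and 3.45), tropomyosin TPM2 (3.41 and 3.37) and the GDP dissociation inhibitor ARHGDIB (3.15 and at least 3.13). Lower on both pairs were the brain angiogenesis inhibitor gene ADGRB1 (-2.12 and -2.09), the melanosome gene PMEL (-2.09 and -2.26), the protocadherin PCDH8 (-1.66 and -1.70), the lactate transporter SLC16A3 (-1.72 and -2.19) and the retinoic acid-binding protein CRABP2 (-1.37 and -1.44).

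The third pattern, weighed with tests chosen after the values they measure had been seen, is that interferon response genes were lower in the combination than under 5-aza-dC (median -0.75). A weaker 5-aza-dC effect on all genes of the combination culture is argued against by the cancer-testis antigens, whose median between the same arrays was 0.072 (quartiles -0.016 and 0.19, 22 genes). Other genes higher under 5-aza-dC had -0.12 (quartiles -0.43 and 0.081, 262 genes outside the interferon and MHC lists, called with signals below 100 units raised to 100), where those lists had -0.57. Those 262 genes were picked for a high reading on the same 5-aza-dC array, which by itself favours values below 0 here. Their median therefore cannot tell whether the effect was weaker on them. A weaker effect on part of the 5-aza-dC genes stays open. The list was also lower in TBT against mock, which does not use the 5-aza-dC array, with a median of -0.31, below all matched random lists. That comparison shares no array with the combination against 5-aza-dC, so it cannot tell whether the 5-aza-dC array read high. An effect of TBT that lowers interferon response transcripts with and without 5-aza-dC is a hypothesis these values are consistent with. It cannot be told apart from a difference between cultures other than the compounds, because there is 1 array per group.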
